A study of Anas platyrhynchos with 16 samples.

How the data were processed

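RNA sequencing libraries from hypothalamus and pituitary of caged and floor-water Shanma ducks were analysed, 4 for each tissue and housing and 16 in all. Per the labels, RNA integrity numbers were above 7.0 and the libraries followed standard Illumina protocols; strandedness and read length were not given in the sources used here. The submitters' processing notes name cutadapt, HISAT2, StringTie 1.3.4d and DESeq2, without settings, order or annotation, and the genome build was not given in the sources used here. Gene positions are therefore not printed.

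Whole-number counts per gene were deposited by the authors for each library, per the file headers. The authors also deposited FPKM, fragments scaled by transcript length and library size, and list genes without signal at 0.0001. The authors' deposited comparison tables give a fold (as the values show, the ratio of mean caged to mean floor-water FPKM), its log2 value, and a p-value and a q-value for each gene and tissue. Which tool made those p-values was not given in the sources used here. In 100% of entries the authors' own mark of significance equalled an unadjusted p under 0.05 together with a log2 fold of at least 1 in size. Because counts were deposited, the count test was used as the main test, as the design written before the data were examined had it for that case, with limma on FPKM as the alternative.

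The table holds 24263 genes, and 12545 carried a symbol. Gene identifiers were looked up in a reference gene table of the assembly IASCAAS_PekinDuck_T2T, used for names only: 17816 (73.4%) matched, and 537 of the 11863 genes listed by a locus number gained a symbol. Every sample column could be assigned to a labelled sample, and 0 entries named no gene. Reads shared between near-identical genes, such as ribosomal protein copies, may be split differently by other counters, so single members of such families are uncertain. The same holds for overlapping and antisense genes, since strand use is not known.

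Library totals ranged from 38853215 to 67175356 counts, so that counting error is small for all but the lowest genes and the spread between libraries sets the precision. No libraries of a group were duplicates: chi-square statistics per degree of freedom between libraries of the same group were 72.2 to 539. The labels do not say that each library comes from a separate bird, so the p-values measure only the spread between these libraries, which may be technical. Per the labels the caged birds were kept in 3 cages, and the labels read here name no batch. Which cage a library comes from is not given, so libraries may share a cage and may not be independent replicates of housing. No test took the cage into account.

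Within each tissue, caged and floor-water libraries were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling and the filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are caged minus floor-water on the log2 scale, and their standard errors were taken from the fold change and its test statistic. Levels are CPM, counts scaled to TMM-adjusted library sizes. The difference between tissues was tested as an interaction over all 16 libraries. Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 FPKM with pseudocounts of 0.1 and 0.5, other filters (none, or a mean FPKM of 0.5 or 2), quantile and median ratio scaling, robust quasi-likelihood fits, array weights, all libraries in 1 fit, the title number as a block, genes with a symbol only, a log2 fold change of at least 1, and each library left out in turn. Limma on FPKM with a pseudocount of 1 was the design's test for data without counts. Its use beside edgeR was added after the data were seen, as were the newer quasi-likelihood fit and DESeq2 for the difference between tissues. The other-tissue share as a covariate (centred log2 values) and fits without the libraries that stand apart were added then too. The estimated correlation for the difference between tissues, a comparison of genes at least 10 times higher in the other tissue, and a pairing check over genes with a mean CPM of at least 1 were also added then.

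Gene lists, 34 in all, were fixed before the data were examined, and 33 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. No member of the list of mitochondrially encoded genes was found by symbol, so it has no result. For the lists that mark other cell types, the mean log2(FPKM + 1) per library was compared by a two-sided exact permutation test over all 70 assignments, whose smallest possible p is 0.0286.

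The genes named were set by a rule written before the data were examined. Up to 10 genes each way past the threshold were to be named; with none past it, the rule takes the 5 smallest p-values each way among genes with a symbol, a mean FPKM of at least 1 in a group and groups whose libraries do not overlap. It also takes up to 4 members of each list, those with the smallest p, and a set of hormone, stress, thyroid and clock genes fixed beforehand. AVP, OXT, GNRH1, LHB and HSPA5 matched no symbol in the table, and TH and NPVF were filtered out in the pituitary. Not every gene that the rule takes is reported here.

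The level of the other tissue in each library was estimated after the data were seen. Genes outside every list with a mean of at least 50 CPM in one tissue and under 1% of it in at least 1 library of the other were taken (47 for pituitary, 69 for hypothalamus), and the median of their level relative to that tissue's mean was computed per library. Because the choice rests on the lowest library, these shares rank libraries and are no exact measure of tissue mass.

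The tests were run on simulated counts with 200 genes changed. For the hypothalamus (15246 genes) edgeR recovered 35% of genes changed 2-fold and 79% of those changed 4-fold, for the pituitary (15064 genes) 21% and 70.7%, and for the difference between tissues (16379 genes) 8% and 50%. It called 4, 4 and 3 unchanged genes. DESeq2 called 43, 67 and 30 unchanged genes, so its counts are the more liberal ones. A changed list was recovered in each comparison with both correlations, and 0 of 30 unchanged lists were called. Genes were simulated independently, whereas real lists had estimated correlations such as 0.724 (ribosomal proteins, pituitary). The simulation therefore does not measure false list calls in these data.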

Results

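Gene expression was measured by RNA sequencing in the hypothalamus, the brain region that governs hormone release by the pituitary, and in the pituitary of Shanma ducks (Anas platyrhynchos) at 113 days of age. From day 110, 3 days earlier, 15 ducks had been housed in 3 cages measuring 100 × 45 × 50 cm, and 15 ducks had stayed in a system combining floor and water (floor-water ducks). The caged birds received 16 h of light a day and the floor-water birds natural light, so housing and lighting differ together. The series compares expression between both housing systems in each tissue. Each tissue and housing had 4 libraries, with total counts per library of 39213327 to 58219259 in caged hypothalamus and 38853215 to 59413096 in floor-water hypothalamus. Totals were 48433586 to 67175356 in caged pituitary and 53476789 to 65601674 in floor-water pituitary. Values below are means ± SD over n = 4 libraries per group unless stated, and fold changes are caged relative to floor-water on the log2 scale.

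Tissue identity was examined first. Growth hormone (GH1) reached 93200 ± 34800 FPKM in caged and 108000 ± 26300 FPKM in floor-water pituitary, and myelin basic protein (MBP) 2300 ± 673 and 2580 ± 1150 FPKM in caged and floor-water hypothalamus against 25.9 ± 47.3 and 37.4 ± 43.6 FPKM in the pituitary groups. Pituitary transcripts were also present in hypothalamus libraries, unevenly. GH1 stood at 5760 ± 7540 FPKM in caged hypothalamus (16900 FPKM in library 4, 29.1 FPKM in library 2) and 436 ± 498 FPKM in floor-water hypothalamus. Over 47 pituitary-restricted genes, the median level in caged hypothalamus libraries 1 to 4 was 3.51%, 0.877%, 4.88% and 20.5% of the pituitary mean, and in floor-water libraries 1.56%, 0.511%, 0.785% and 0.696%. Over 69 hypothalamus-restricted genes, the pituitary libraries carried 0.481%, 5.60%, 0.417% and 0.29% of the hypothalamus mean when caged and 1.03%, 5.60%, 0.615% and 6.14% when floor-water. Transthyretin (TTR), a choroid plexus transcript, was at 20500 FPKM in caged hypothalamus library 2 and between 8.61 and 662 FPKM in the other caged hypothalamus libraries.

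**Figure D1:**
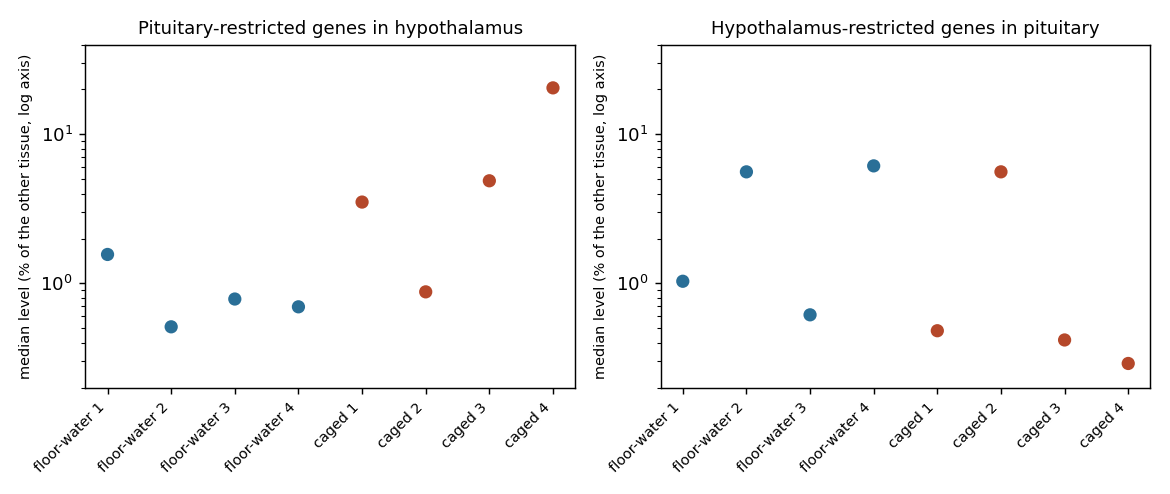
Transcripts of the other tissue per library. Each point is 1 library, the vertical axis is the median level of tissue-restricted genes as a percentage of their mean in the other tissue on a log axis (left, 47 pituitary-restricted genes in hypothalamus; right, 69 hypothalamus-restricted genes in pituitary), with floor-water libraries in blue and caged libraries in red. Caged hypothalamus library 4 stands highest at 20.5%.

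In the hypothalamus, genes of motile cilia and of the extracellular matrix rose as groups in caged ducks. All 18 measured cilium genes lay above 0, with a median fold change of 1.02 (camera adjusted p = 3.81e-15 with the preset correlation, adjusted p = 0.344 with an estimated correlation). CFAP43, a cilium- and flagellum-associated protein, was at 7.27 ± 1.85 CPM in caged and 2.92 ± 0.831 CPM in floor-water libraries (fold change 1.32 ± 0.28 SE), CFAP52 at 16.9 ± 4.41 against 8.54 ± 1.92 CPM, and SPAG6, a central-apparatus protein of the axoneme, at 25.6 ± 2.96 against 16.5 ± 3.41 CPM. Of the 30 extracellular matrix genes 24 lay above 0, with a median of 0.50 (camera adjusted p = 6e-11 preset, adjusted p = 0.191 with an estimated correlation). The fibrillar collagen gene COL1A2 stood at 54.9 ± 21.3 against 19.2 ± 3.35 CPM, COL6A2 at 6.71 ± 1.84 against 2.04 ± 0.668 CPM, and the matrix protease MMP2 at 14.6 ± 3.54 against 7.22 ± 1.13 CPM. Over all genes tested in edgeR no member of either list passed the threshold, while adjusted over the list alone 11 cilium genes and 12 matrix genes were higher and 0 lower. With the pituitary share of each library as a covariate the medians were 1.45 and 0.57, and without caged libraries 2 and 4 they were 1.16 and 0.42. Quantile normalisation in limma gave 0.575 and 0.28, and limma on FPKM 0.65 for the cilium genes; both lists kept their calls at the preset correlation in each of these fits.

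**Figure D2:**
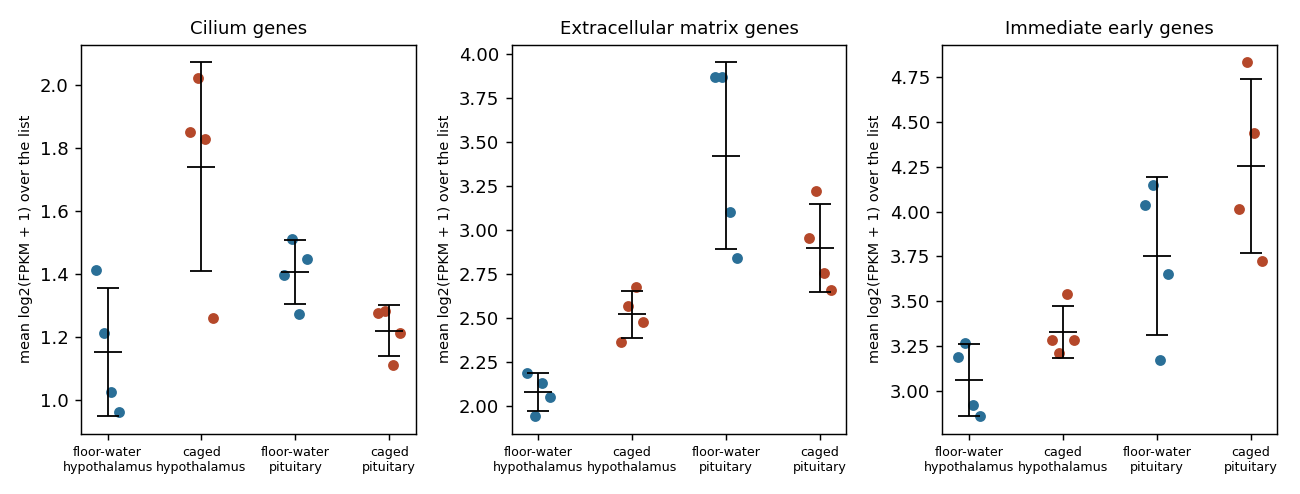
Levels of 3 gene lists per library. Points are libraries (floor-water blue, caged red), the vertical axes give the mean log2(FPKM + 1) over the list, and horizontal bars with whiskers are group means ± SD of 4 libraries. Extracellular matrix levels in caged hypothalamus (2.36 to 2.68) all lie above those in floor-water hypothalamus (1.94 to 2.19).

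Ribosomal protein genes also rose in caged hypothalamus, 64 of 66 lying above 0 with a median of 0.26 (camera adjusted p = 7.93e-14 preset, adjusted p = 0.408 with an estimated correlation). RPLP1 was at 620 ± 53.0 CPM against 469 ± 30.9 CPM and RPL23 at 625 ± 68.9 CPM against 476 ± 25.2 CPM. Nuclear-encoded genes of oxidative phosphorylation fell, 61 of 64 lying below 0 with a median of -0.17 (adjusted p = 1.06e-09 preset, adjusted p = 0.408 with an estimated correlation), among them the complex I subunit NDUFS7 at 109 ± 12.7 against 145 ± 16.4 CPM and COX6C at 202 ± 10.7 against 251 ± 26.3 CPM. Neuron markers fell with a median of -0.18 and 13 of 14 below 0 (adjusted p = 0.0058 preset, adjusted p = 0.568 with an estimated correlation). The synaptic protein SNAP25 was at 1341 ± 289 against 1830 ± 174 CPM. Genes of GABA and glutamate signalling fell with a median of -0.16 and 27 of 35 below 0 (adjusted p = 0.00106 preset, adjusted p = 0.408 with an estimated correlation). The metabotropic receptor GRM3 was at 146 ± 5.13 against 184 ± 8.87 CPM. Over all libraries, mean log2(FPKM + 1) in hypothalamus and pituitary was 8.18 and 9.43 for ribosomal and 7.58 and 7.22 for oxidative phosphorylation genes. It was 6.81 and 3.55 for neuron markers and 4.34 and 1.31 for GABA and glutamate genes. Pituitary tissue would thus move all 4 lists the way seen, and caged library 4 held a pituitary share of 20.5%. With that share as a covariate the ribosomal median was 0.11 and the oxidative phosphorylation median -0.13, both still called, while the neuron median (0.073) and the GABA and glutamate median (-0.11) were not. Of these 4 lists 0 members passed when adjusted over the list alone.

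Pituitary genes were higher in caged hypothalamus together with the pituitary share. The list of pituitary hormones and lineage factors rose with a median of 1.49 and 23 of 27 above 0 (adjusted p = 1.92e-09 preset, adjusted p = 0.344 with an estimated correlation), and the reproductive axis list with a median of 1.01 and 19 of 23 above 0 (adjusted p = 2.42e-05 preset, adjusted p = 0.36 with an estimated correlation). PRL, which encodes prolactin, was at 3432 ± 4249 against 176 ± 226 CPM, POMC, the precursor of corticotropin and melanocortins, at 1296 ± 1364 against 104 ± 130 CPM, and TBX19, a corticotroph transcription factor, at 7.05 ± 6.80 against 0.3 ± 0.184 CPM. The photoperiod and thyroid hormone list, which contains the pituitary genes CGA and CHGA and the choroid plexus gene TTR, rose with a median of 0.43 and 18 of 21 above 0 (adjusted p = 0.000411 preset, adjusted p = 0.344 with an estimated correlation). SLCO1C1, a thyroid hormone transporter, was at 43.5 ± 55.6 against 0.568 ± 0.425 CPM, with 120 CPM in caged library 3 and 48.9 CPM in caged library 2. Folliculostellate and pituitary stem cell markers rose with a median of 0.36 and 10 of 11 above 0 (adjusted p = 0.000411 preset, adjusted p = 0.344 with an estimated correlation). With the pituitary share as a covariate none of these 4 lists was called, and their medians were -0.123, 0.036, -0.03 and 0.15. All 4 kept their calls without caged library 4 (1.10, 0.76, 0.40 and 0.395) and without caged libraries 2 and 4 (1.22, 0.73, 0.40 and 0.29), where the caged libraries left held pituitary shares of 3.51% and 4.88% against 0.511% to 1.56% in floor-water libraries. Adjusted over the list alone, 3 of the hormone and lineage genes and 1 each of the photoperiod and folliculostellate lists were higher, and 0 of the reproductive list.

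Immediate early genes, which respond within minutes to cell activation, rose in caged hypothalamus with a median of 0.27 and 15 of 21 above 0 (adjusted p = 0.0102 preset, adjusted p = 0.476 with an estimated correlation), with KLF4 at 2.51 ± 0.23 against 0.924 ± 0.23 CPM. Glucocorticoid response genes rose with a median of 0.17 and 13 of 19 above 0 (adjusted p = 0.0258 preset, adjusted p = 0.408 with an estimated correlation). Among them CEBPD was at 14.2 ± 9.56 against 3.51 ± 1.87 CPM and FKBP5, a glucocorticoid receptor co-chaperone, at 159 ± 97.6 against 91.8 ± 33.3 CPM. Both lists had higher mean log2(FPKM + 1) in pituitary than in hypothalamus (4 against 3.19 and 4.95 against 3.97). Neither list was called with the pituitary share as a covariate (medians 0.18 and 0.20). Without caged libraries 2 and 4 the glucocorticoid median was -0.015. When adjusted over the list alone 1 immediate early gene and 0 glucocorticoid response genes were higher. The remaining 21 lists were not called in the hypothalamus. Their medians ranged from -0.28 (erythrocyte markers) to 0.41 (T and B lymphocyte markers). The circadian clock list had a median of -0.15 (adjusted p = 0.19 preset) and the stress axis list 0.03 (adjusted p = 0.367 preset). The stress axis, neuropeptide and feeding lists had means of 0.73, 0.58 and 0.47 beside medians of 0.03, 0.10 and 0.04, heat shock genes a median of -0.11 beside a mean of 0.04, monoamine genes -0.08 beside 0.03, and photoreceptor and pineal markers -0.04 beside 0.16.

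Among single genes of the hypothalamus, 0 of 15736 passed an adjusted p of 0.05 in edgeR, 1463 had an unadjusted p under 0.05 (889 higher, 574 lower; 965 with the pituitary share as a covariate), and DESeq2 called 243 (192 higher, 51 lower). Genes higher in caged libraries made up 60.8% of those at an unadjusted p under 0.05, against 73.2% with limma on FPKM (0 called) and 51.3% with quantile normalisation in limma (1 called, GPX3). Without floor-water library 2, edgeR called 1 gene, LOC113842051, singled out after its values were seen. The smallest p-values upward belonged to GPX3, an extracellular glutathione peroxidase (gene 101804134; 570 ± 65.5 against 321 ± 19.8 CPM, fold change 0.83 ± 0.10 SE, edgeR adjusted p = 0.281), BSPRY (101793618; 46.5 ± 1.05 against 28.1 ± 2.50 CPM), KAZALD1 (101790967; 4.37 ± 2.09 against 0.702 ± 0.0532 CPM), EZR, which links membrane to actin (101796544; 73.9 ± 19.4 against 32.9 ± 3.27 CPM), and the unconventional myosin MYO7A (101796115; 43.6 ± 4.17 against 26.2 ± 3.50 CPM). Those downward belonged to RUNDC1 (36.5 ± 6.20 against 67.1 ± 8.15 CPM), FRMD4B (7.35 ± 0.514 against 13.1 ± 1.35 CPM), NYAP2 (24.7 ± 2.54 against 41.5 ± 6.03 CPM), RGS8, a regulator of G protein signalling (206 ± 31.7 against 397 ± 87.0 CPM), and the orphan receptor GPR158 (272 ± 27.9 against 383 ± 11.1 CPM). The rule took these 10 only from genes with a symbol, a mean FPKM of at least 1 in a group and groups that do not overlap. Over all genes tested, groups did not overlap for 895 (5.69%, where chance gives 2.86%). None of the 10 passed the threshold in edgeR, while all 10 did in DESeq2. Of the genes fixed beforehand, corticotropin-releasing hormone (CRH) was at 33.1 ± 18.1 against 83.7 ± 40.8 CPM (fold change -1.34 ± 0.50 SE, edgeR adjusted p = 0.48) and the clock gene PER3 at 21.8 ± 4.60 against 12.4 ± 2.42 CPM (0.82 ± 0.20 SE, edgeR adjusted p = 0.361). DIO2 and DIO3, which activate and inactivate thyroid hormone, were at 91.3 ± 31.0 against 67.7 ± 10.6 CPM and 4.67 ± 7.32 against 0.557 ± 0.408 CPM. NPVF, the precursor of gonadotropin-inhibitory hormone, was at 155 ± 190 against 31.9 ± 61.3 CPM. VIP, TRH, TH, NR3C1, TSC22D3, PER2, CRY1, NR1D2, FOS, EGR1, HSP90AA1 and TSHB had fold changes between -0.79 and 0.83, none past the threshold.

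Several hypothalamus list calls rested on single libraries. The glucocorticoid list lost its call without caged library 2 (median 0.09), caged library 4 (0.12) or floor-water library 4 (0.09), and the immediate early list without caged library 3 (0.16), floor-water library 3 (0.19) or floor-water library 4 (0.16); without floor-water library 2 the latter had a median of 0.415. The GABA and glutamate list lost its call without caged library 4 (-0.13) and had medians of -0.26 and -0.24 without caged libraries 1 and 3. The neuron list lost its call without caged library 3 (-0.145) or 4 (-0.07) and had medians of -0.30 and -0.11 without caged library 2 and floor-water library 2. Without caged library 4 the ribosomal median was 0.15, and without caged library 3 the photoperiod median was 0.28, both still called. Settings also ended calls. The glucocorticoid call was lost in limma with pseudocounts of 0.1 (0.20), 0.5 (0.20) and 1 (0.19) and with array weights (0.13), and the neuron call with quantile normalisation (-0.15) and array weights (-0.07). With all libraries in 1 fit the glucocorticoid (0.18), immediate early (0.28) and GABA and glutamate (-0.15) calls were lost, and without caged libraries 2 and 4 the neuron (-0.12) and GABA and glutamate (-0.09) calls. Calls were kept with quantile normalisation for reproductive axis (0.37), photoperiod (0.25) and oxidative phosphorylation genes (-0.11), and with array weights for reproductive axis (0.40) and hormone genes (0.835).

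In the pituitary, immediate early genes stood higher as a list in caged libraries and extracellular matrix genes lower, with library levels overlapping in both lists. Mean immediate early levels were 4.02, 4.83, 4.44 and 3.72 in caged libraries 1 to 4 on the log2(FPKM + 1) scale. In floor-water libraries 1 to 4 they were 4.04, 4.15, 3.17 and 3.65. Of 21 immediate early genes 18 lay above 0, with a median of 0.70 (camera adjusted p = 1.84e-09 preset, adjusted p = 0.431 with an estimated correlation). FOS was at 329 ± 113 against 116 ± 69.7 CPM (fold change 1.51 ± 0.47 SE), EGR1 at 922 ± 480 against 333 ± 177 CPM (1.47 ± 0.50 SE), NR4A1, an orphan nuclear receptor that takes part in POMC transcription, at 253 ± 209 against 59.8 ± 24.0 CPM, and JUND at 221 ± 53.5 against 127 ± 21.6 CPM. Without caged library 2, which held 522 CPM of NR4A1 and a brain share of 5.60%, the median of the list was 0.28 and it was still called, as it was with array weights in limma (0.40) and without the 3 libraries richest in brain transcripts (0.39). All 30 extracellular matrix genes lay below 0, with a median of -0.67 (adjusted p = 9.46e-13 preset, adjusted p = 0.431 with an estimated correlation). COL5A2 was at 13.9 ± 4.41 against 28.9 ± 11.5 CPM, fibronectin (FN1) at 33.6 ± 6.09 against 58.9 ± 20.1 CPM and SPARC at 481 ± 66.6 against 763 ± 226 CPM. Mean matrix levels in floor-water libraries 1 and 2 were 3.87 each on the log2(FPKM + 1) scale and in the other two 3.10 and 2.84, against 2.66 to 3.22 in caged libraries. Floor-water libraries 1 and 2 were also the highest of the 8 for microglia (3.16 and 3.015) and erythrocyte markers (1.58 and 2.225), and library 1 for skeletal muscle markers (2.36). With the brain share of each library as a covariate the medians were 0.83 for immediate early genes and -0.61 for matrix genes. Adjusted over the list alone, 0 members of either list passed.

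Smaller rises in list medians concerned metabolism and proteostasis, while library levels overlapped between housings in all 4 lists. Mean log2(FPKM + 1) was 3.655 to 4.16 caged against 3.695 to 3.93 floor-water for sterol genes. It was 4.80 to 5.27 against 4.57 to 5.14 for heat shock and 1.425 to 2.73 against 1.79 to 2.34 for cell cycle genes. Oxidative phosphorylation genes were at 7.105 to 7.50 against 7.17 to 7.23, with caged libraries 1 and 3 lowest. Sterol biosynthesis genes rose with a median of 0.18 and 18 of 22 above 0 (adjusted p = 0.000408 preset, adjusted p = 0.431 with an estimated correlation), with HMGCS1, an early enzyme of the mevalonate pathway, at 174 ± 43.0 against 102 ± 17.3 CPM and squalene epoxidase (SQLE) at 56.8 ± 10.9 against 42.6 ± 3.76 CPM. Heat shock genes and chaperones rose with a median of 0.16 and 21 of 26 above 0 (adjusted p = 0.00167 preset, adjusted p = 0.457 with an estimated correlation). DNAJB5 was at 62.1 ± 24.3 against 30.7 ± 5.52 CPM and HSPA8 at 3420 ± 722 against 2479 ± 265 CPM. Nuclear-encoded oxidative phosphorylation genes rose with a median of 0.12 and 52 of 64 above 0 (adjusted p = 0.000798 preset, adjusted p = 0.78 with an estimated correlation), NDUFA5 being at 75.4 ± 10.9 against 57.7 ± 3.81 CPM. Cell cycle genes rose with a median of 0.28 and 25 of 31 above 0 (adjusted p = 0.028 preset, adjusted p = 0.793 with an estimated correlation), the replication helicase subunit MCM6 being at 75.7 ± 21.6 against 53.3 ± 4.87 CPM. With the brain share as a covariate the oxidative phosphorylation call was lost (median 0.04), and without the 3 libraries richest in brain transcripts the heat shock (0.12), oxidative phosphorylation (0.03) and cell cycle (-0.014) calls were lost. With array weights in limma the heat shock and oxidative phosphorylation medians were -0.037 and -0.026, not called. Adjusted over the list alone, 0 members of these 4 lists passed.

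Genes of several brain cell types, but not neuron markers, fell in caged pituitary, where brain shares were 5.60% and 6.14% in floor-water libraries 2 and 4 and 5.60% in caged library 2. Hypothalamic neuropeptides had a median of -1.08 with 16 of 20 below 0 (adjusted p = 0.00167 preset, adjusted p = 0.457 with an estimated correlation). AGRP, an appetite-stimulating peptide, was at 0.367 ± 0.165 against 3.89 ± 6.86 CPM. The floor-water AGRP mean rested on library 2, at 12.3 FPKM against 0.0723 to 0.543 FPKM in the other floor-water libraries. GABA and glutamate genes had a median of -0.56 with 29 of 35 below 0 (adjusted p = 6.87e-05 preset, adjusted p = 0.646 with an estimated correlation). Feeding genes had a median of -0.35 (25 of 29 below 0, adjusted p = 0.00128 preset, adjusted p = 0.431 with an estimated correlation) and oligodendrocyte markers -0.44 (15 of 17, adjusted p = 0.00167 preset, adjusted p = 0.457 with an estimated correlation). Astrocyte and tanycyte markers had a median of -0.52 (12 of 15, adjusted p = 0.000798 preset, adjusted p = 0.431 with an estimated correlation), the glutamate transporter SLC1A2 being at 2.2 ± 0.413 against 6.67 ± 3.83 CPM. Cilium genes had a median of -0.31 (14 of 18, adjusted p = 0.00278 preset, adjusted p = 0.431 with an estimated correlation) and choroid plexus markers -0.44 (10 of 13, adjusted p = 0.00843 preset, adjusted p = 0.431 with an estimated correlation). With the brain share as a covariate none of these 7 lists was called, and their medians ranged from -0.33 to -0.05. Medians moved most for neuropeptides (-0.33) and GABA and glutamate genes (-0.05). They moved less for astrocyte (-0.30), oligodendrocyte (-0.33), cilium (-0.24) and feeding genes (-0.32). Without the 3 libraries richest in brain transcripts neuropeptide (-0.56), GABA and glutamate (-0.32), oligodendrocyte (-0.585) and astrocyte genes (-0.44) were still called, and feeding (-0.32), cilium (-0.195) and choroid plexus genes (-0.38) were not. Neuron markers were not called (median -0.10) and with that covariate were called higher (0.285, camera adjusted p = 0.000358 preset). At the preset correlation the covariate also brought endothelial markers (-0.34, camera adjusted p = 0.0253) and the stress axis (0.02, camera adjusted p = 0.0328) past the threshold. Without the 3 libraries richest in brain transcripts the stress axis was called too (0.34, camera adjusted p = 0.03345). With an estimated correlation both fits called 0 lists. In the 7 lists 1 GABA and glutamate gene and 1 cilium gene were lower when adjusted over the list alone, and 0 genes of the other lists passed.

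Muscle and macrophage markers fell as well. Skeletal muscle markers had a median of -0.78 with 15 of 15 below 0 (adjusted p = 8.22e-05 preset, adjusted p = 0.431 with an estimated correlation), and myoglobin (MB) was at 1.01 ± 0.726 against 13.4 ± 19.5 CPM. Without floor-water library 1 the muscle median was -0.18 and the call was lost. Microglia and macrophage markers had a median of -0.38 with 14 of 16 below 0 (adjusted p = 0.026 preset, adjusted p = 0.693 with an estimated correlation), with the complement gene C1QC at 10.5 ± 4.24 against 18.6 ± 5.90 CPM. Over all alternatives run, the microglia median ranged from -0.67 to -0.15 and the muscle median from -1.92 to -0.18. The remaining 18 lists were not called in the pituitary. Their medians ranged from -0.47 (erythrocyte markers) to 0.06 (pituitary hormones and lineage factors), and the circadian clock list had a median of -0.04 (adjusted p = 0.0608 preset). Median and mean had opposite signs for the stress axis (0.01 and -0.085), glucocorticoid response (0.01 and -0.08), inflammation (-0.035 and 0.20) and hypoxia (-0.05 and 0.04) lists, and the tests of the neuron (median -0.10) and photoperiod (median -0.07) lists pointed upward.

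Hormone and clock genes fixed beforehand were examined in the pituitary. PRL was at 65950 ± 27430 CPM in caged and 32860 ± 4365 CPM in floor-water libraries, with every caged library above every floor-water one (fold change 1.005 ± 0.26 SE, edgeR adjusted p = 0.973). The common glycoprotein hormone subunit CGA was at 14690 ± 4313 against 8620 ± 2398 CPM (0.77 ± 0.26 SE, edgeR adjusted p = 0.9996, DESeq2 adjusted p = 0.333). The clock gene PER2 was at 24.7 ± 4.59 against 47.4 ± 12.2 CPM (-0.94 ± 0.22 SE, edgeR adjusted p = 0.961, DESeq2 adjusted p = 0.045) and CRY1 at 65.4 ± 8.40 against 89.4 ± 13.7 CPM (-0.45 ± 0.16 SE). The glucocorticoid-induced gene TSC22D3 was at 150 ± 45.1 against 225 ± 51.8 CPM (-0.59 ± 0.24 SE). GH1, POMC, TSHB and FSHB had fold changes of -0.17, 0.07, -0.37 and -0.49. None of these passed the threshold in edgeR, and adjusted over the list alone 1 clock gene was lower. Of the glucocorticoid response list 1 gene was higher and 3 were lower by that measure.

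**Figure D3:**
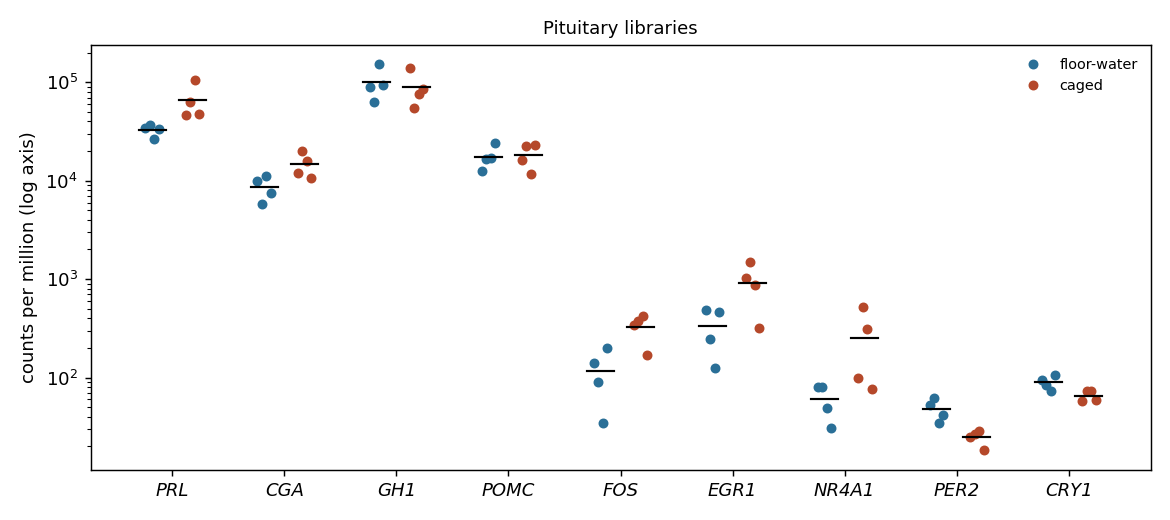
Hormone, immediate early and clock genes in the pituitary. Points are libraries (floor-water blue, caged red), black bars are means of 4 libraries, and the vertical axis is CPM on a log axis. PRL averages 65950 CPM in caged and 32860 CPM in floor-water libraries, and PER2 24.7 and 47.4 CPM.

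In the pituitary 0 of 15582 genes passed an adjusted p of 0.05 in edgeR, 670 had an unadjusted p under 0.05 (266 higher, 404 lower), and DESeq2 called 52 (16 higher, 36 lower). Genes higher in caged libraries made up 39.7% of those at an unadjusted p under 0.05, against 26.1% with limma on FPKM (0 called) and 48.3% with quantile normalisation in limma (0 called). Groups did not overlap for 412 genes (2.64%, where chance gives 2.86%). The smallest edgeR adjusted p was 0.104 over all genes and 0.958 in a fit of genes with a symbol only. Genes were named only if they had a symbol, a mean FPKM of at least 1 in a group and groups that do not overlap. Among these the smallest p-values upward were those of GRIN2C, an NMDA receptor subunit (8.25 ± 2.71 against 1.85 ± 0.825 CPM, fold change 2.16 ± 0.40 SE, edgeR adjusted p = 0.961), the ubiquitin protease USP34 (41.7 ± 4.80 against 25.3 ± 2.12 CPM), FMNL1, a formin (60.3 ± 18.6 against 26.5 ± 6.07 CPM), the PI3-kinase regulatory subunit PIK3R3 (127 ± 26.9 against 71.8 ± 8.93 CPM) and NFAT5, a transcription factor of the osmotic response (155 ± 31.6 against 48.5 ± 31.5 CPM). Those downward were RPIA of the pentose phosphate pathway (25.1 ± 1.43 against 54.2 ± 13.2 CPM), the lipid droplet protein PLIN2 (29.5 ± 2.90 against 55.5 ± 12.9 CPM), the AMPA receptor subunit GRIA3 (3.46 ± 1.64 against 10.1 ± 1.57 CPM), TBX3 (12.7 ± 1.92 against 22.9 ± 3.23 CPM) and the endothelial adhesion molecule SELE (0.793 ± 0.369 against 3.73 ± 1.85 CPM). None of the 10 passed the threshold in edgeR, and all 10 passed it in DESeq2. Without floor-water library 3, NFAT5 (fold change 2.26, edgeR adjusted p = 0.0212) and PPM1L, singled out after its values were seen, passed in edgeR.

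Single libraries also moved pituitary list results. Without floor-water library 2 the calls for neuropeptides (median 0.07), GABA and glutamate (-0.39), feeding (-0.24), astrocyte (-0.25), oxidative phosphorylation (0.04), cell cycle (0.29), choroid plexus (-0.42) and microglia (-0.32) genes were lost. Without caged library 2 those for heat shock (0.06), cell cycle (0.13) and microglia (-0.25) were lost, and the medians of sterol, neuropeptide, GABA and glutamate, oligodendrocyte, choroid plexus and muscle genes were 0.06, -1.72, -0.98, -1.26, -0.70 and -1.68. Without caged library 4 those for oxidative phosphorylation (0.01), choroid plexus (-0.35) and microglia (-0.29) were lost, with medians of 0.55 for cell cycle and -0.69 for neuropeptides. Without caged library 1 the neuropeptide call was lost (-0.78) and the muscle median was -0.48, and without caged library 3 the cell cycle call was lost (0.09) and the oligodendrocyte and microglia medians were -0.24 and -0.62. Without floor-water library 1 the cell cycle (0.28), choroid plexus (-0.46) and microglia (-0.15) calls were lost, with medians of 0.11 for sterol and -0.71 for oligodendrocyte genes. Without floor-water library 4 the cell cycle (0.28) and oligodendrocyte (-0.19) calls were lost, with medians of -0.34 for GABA and glutamate and -0.61 for microglia. Without floor-water library 3 the medians of sterol, oxidative phosphorylation, cell cycle and cilium genes were 0.31, 0.26, 0.64 and -0.50. In limma with pseudocounts of 0.1, 0.5 and 1 the cilium (-0.26, -0.24 and -0.21), choroid plexus (-0.50, -0.375 and -0.27) and microglia (-0.42, -0.40 and -0.33) calls were lost. Quantile normalisation ended the heat shock (0.08), oxidative phosphorylation (0.03), cilium (-0.12) and choroid plexus (-0.14) calls, and array weights the choroid plexus (-0.29) and microglia (-0.25) calls. The cell cycle call was lost with a pseudocount of 0.1 (0.04), without a filter (0.26), with a filter of mean FPKM 0.5 (0.23) and with all libraries in 1 fit (0.26). Still called were neuropeptides (-0.415), GABA and glutamate (-0.25) and feeding genes (-0.19) with quantile normalisation, sterol genes in limma on FPKM (0.09) and muscle markers with a filter of mean FPKM 0.5 (-1.80).

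The effect of caging was then compared between the tissues. Extracellular matrix genes had the smallest adjusted p, with a median difference (pituitary minus hypothalamus) of -1.10 with 29 of 30 below 0 (camera adjusted p = 1.39e-20 preset, adjusted p = 0.0885 with an estimated correlation), followed by cilium genes at -1.29 with 18 of 18 below 0 (adjusted p = 2.23e-15 preset, adjusted p = 0.0885 with an estimated correlation). Adjusted over the list alone, 15 matrix and 9 cilium genes differed downward and 0 upward. SPAG6 had a fold change of 0.63 in hypothalamus and -1.43 in pituitary, and COL1A2 a difference of -2.39. Oxidative phosphorylation genes differed the other way, with a median of 0.28 and 63 of 64 above 0 (adjusted p = 2.1e-12 preset, adjusted p = 0.369 with an estimated correlation). In all, 17 lists were called (4 upward, 13 downward) and 0 with an estimated correlation. Among them, the lists of pituitary and brain genes may follow the shares of the other tissue given above. This was not tested, since no fit of the difference took those shares as covariates. Of 17010 genes 0 passed an adjusted p of 0.05 in edgeR, 1226 had an unadjusted p under 0.05 (314 upward, 912 downward), and DESeq2 called 142 (13 upward, 129 downward). The share upward was 25.6%, against 11.4% with limma on FPKM (0 called) and 52.6% with quantile normalisation in limma (0 called). The smallest edgeR adjusted p was 0.139. PER2 and FOS had differences of -0.77 and 1.21. Without caged hypothalamus library 2, caged pituitary library 2 or floor-water pituitary library 3, edgeR called 1 (LOC106015636), 3 (CHRNA6, GRIA3, LOC113843915) and 4 genes (GRPR, LOC101799801, SPAG6, CTXND1), named after their values were seen. Without caged pituitary library 4 the oxidative phosphorylation median was 0.14, still called. With quantile normalisation the cilium and oxidative phosphorylation medians were -0.69 and 0.15, and with array weights the latter was 0.09, all still called. Median and mean differed in sign for heat shock (0.17 and -0.06), cell cycle (0.17 and -0.02) and inflammation (-0.25 and 0.01) genes, and the clock list (median 0.15) had a test pointing downward.

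No gene was called in both tissues, since edgeR called 0 in each. At an unadjusted p under 0.05, 1408 genes in hypothalamus and 648 in pituitary among the 14683 tested in both gave 42 genes higher in both, where independent lists give 15, and 27 lower in both, where they give 14.6. Another 46 had opposite directions, where independent lists give 32.6. These expected counts take the tissues as independent, and so does a reading of the correlations below against 0. The labels do not say whether equal numbers mark the same birds, and equal-numbered libraries of the tissues correlated at 0.077 to 0.173, so birds shared between tissues, which could raise the counts in the same direction and the correlations, are not excluded. Across these genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.079 and a Spearman correlation of 0.094.

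Cell type marker levels per library were compared by exact permutation over the 4 caged and 4 floor-water libraries of each tissue. In hypothalamus the smallest possible p, 0.0286, was reached by endothelial markers (2.37 ± 0.083 against 2.15 ± 0.065 mean log2(FPKM + 1), exact adjusted p = 0.172) and folliculostellate markers (2.91 ± 0.364 against 2.43 ± 0.102, exact adjusted p = 0.172). Cilium genes were at 1.74 ± 0.332 against 1.15 ± 0.204 (exact p = 0.0571, exact adjusted p = 0.228). In pituitary every list had an exact adjusted p of 0.588 or more, muscle markers being at 0.919 ± 0.144 against 1.43 ± 0.644. No marker list passed after adjustment over the 12 lists of a tissue. Lists at the smallest possible p reached only an exact adjusted p of 0.172, so a single list could not have passed. The result therefore does not show that cell type levels are equal.

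The authors' deposited table for hypothalamus marks 506 genes, 445 higher and 61 lower in caged ducks, of which 139 have a q-value under 0.05. The authors' deposited table for pituitary marks 342 genes, 75 higher and 267 lower, of which 37 have a q-value under 0.05. At an adjusted p of 0.05 the edgeR test made here called 0 of them in either tissue, and DESeq2 run here called 243 and 52 genes. The authors' mark rests on an unadjusted p under 0.05 together with a log2 fold of at least 1 in size. By an unadjusted p under 0.05 alone, the authors' deposited values give 910 and 580 genes, and edgeR gave 1463 and 670. Of the marked genes tested here, 376 of 439 higher and 44 of 56 lower ones in hypothalamus had an unadjusted edgeR p under 0.05. In pituitary these were 57 of 74 higher and 190 of 249 lower ones. Both analyses used the same libraries.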

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

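Several tests were chosen only after the data were seen. These were fits with a tissue share as a covariate, without the libraries richest in brain transcripts, or without both caged hypothalamus libraries 2 and 4. They also include the ventricle wall test, the estimated correlation for the difference between tissues, and the use of limma with a pseudocount of 1 beside edgeR.

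Libraries far from the rest of their group appeared in 19 of 336 groups of 4, where chance gives 16.8. In caged hypothalamus, FRMD4B was at 6.58 CPM in library 4 against 7.56 to 7.68 CPM in the other libraries. In floor-water hypothalamus, TH was at 76.2 CPM in library 4 (others 3.55 to 5.83 CPM), PER2 at 58.7 CPM in library 1 (46.1 to 47.8 CPM) and CHGA at 2120 CPM in library 1 (1110 to 1170 CPM). In the same group ESR1 was at 0.872 CPM in library 2 (2.98 to 3.20 CPM), COL6A2 at 3.03 CPM in library 3 (1.61 to 1.78 CPM) and NDUFS7 at 169 CPM in library 2 (135 to 138 CPM). In caged pituitary library 2, RPIA was at 23 CPM (25.5 to 26.0 CPM), PLIN2 at 33.8 CPM (27.6 to 28.4 CPM) and MC4R at 0.796 CPM (0.263 to 0.331 CPM), and in library 1 GABRB2 was at 9.36 CPM (13.6 to 14.5 CPM). In floor-water pituitary library 3, NFAT5 was at 95.6 CPM (29.7 to 35.8 CPM), HMGCS1 at 76.8 CPM (108 to 115 CPM) and ATP5IF1 at 84 CPM (71.3 to 72.9 CPM). MC4R was at 10.1 CPM in floor-water pituitary library 2 (0.275 to 0.654 CPM) and CPT1A at 43.5 CPM in library 1 (18.8 to 21.2 CPM). Mean log2(FPKM + 1) of the neuron list was 4.28 (others 3.24 to 3.29) and of the oligodendrocyte list 2.57 (1.26 to 1.37) in caged pituitary library 2, and that of the choroid plexus list 0.779 in floor-water pituitary library 3 (1.38 to 1.46).

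Caged against floor-water fold changes differed between the tissues for 17 lists by the interaction test at the preset correlation. With an estimated correlation none of them did. No fit of this difference took the tissue shares as covariates, so the part of the other tissue in it was not tested. The median differences, pituitary minus hypothalamus, were 0.351 for immediate early, 0.171 for heat shock, 0.113 for sterol and 0.275 for oxidative phosphorylation genes. They were -1.671 for reproductive axis, -1.524 for pituitary hormone and lineage, -1.162 for neuropeptide, -0.613 for photoperiod, -0.54 for feeding, -1.102 for extracellular matrix, -0.237 for ribosomal protein and -0.634 for astrocyte genes. They were -1.292 for cilium, -0.685 for choroid plexus, -0.58 for microglia, -0.592 for skeletal muscle and -0.87 for folliculostellate genes. Adjusted over the list alone, 1 heat shock gene differed upward. Downward differed 3 hormone, 3 folliculostellate and 1 each of the photoperiod, astrocyte and choroid plexus genes. Calls were lost for immediate early genes without caged pituitary library 2 (0.21), and for feeding (-0.36) and astrocyte genes (-0.36) without floor-water pituitary library 2. They were lost for neuropeptides without caged pituitary library 1 (-0.88) or 4 (-1.07) or floor-water pituitary library 2 (-0.23), and for choroid plexus genes without caged hypothalamus library 2 (-0.41) or caged pituitary library 4 (-0.51). They were lost for microglia without caged pituitary library 2 (-0.45) or floor-water pituitary library 1 (-0.42). The ribosomal call was lost without caged hypothalamus library 4 (-0.13), caged pituitary library 2 (-0.19) or 3 (-0.165) or floor-water pituitary library 3 (-0.12). With array weights or in limma with pseudocounts of 0.1, 0.5 and 1, the neuropeptide, choroid plexus and muscle calls were lost, and with array weights the microglia call (-0.255). Quantile normalisation ended the heat shock (0.15), sterol (0.06), choroid plexus (-0.25) and muscle (-0.445) calls. The sterol call was lost without caged hypothalamus library 4 (0.08), caged pituitary library 2 (-0.002) or floor-water pituitary library 1 (0.015). The muscle call was lost without caged hypothalamus library 1 (-1.06) or 4 (-0.46), floor-water hypothalamus library 1 (-1.12), caged pituitary library 1 (-1.21), 3 (-0.92) or 4 (-1.20), or floor-water pituitary library 1 (-0.55). Other calls kept their side with medians moved by over 1.5 times. These were hormone genes without caged hypothalamus library 4 (-0.92), photoperiod genes without caged hypothalamus library 4 (-0.365), caged pituitary library 1 (-0.39) or floor-water pituitary library 2 (-0.33). Heat shock genes moved without caged hypothalamus library 2 (0.265), choroid plexus genes without floor-water hypothalamus library 4 (-1.185) and oxidative phosphorylation genes without caged pituitary library 4 (0.14). Immediate early genes were at 0.655 without floor-water pituitary library 2, neuropeptides at -0.64, -1.76 and -3.54 without caged hypothalamus library 3, floor-water hypothalamus library 1 and caged pituitary library 2. Ribosomal genes were at -0.38 without caged pituitary library 4, and sterol genes at 0.07, 0.22 and 0.18 without caged pituitary libraries 1 and 4 and floor-water pituitary library 3. Muscle genes were at -1.25 and -1.135 without caged hypothalamus libraries 2 and 3, -1.24 and -1.20 without floor-water hypothalamus libraries 2 and 4, -2.52 without caged pituitary library 2 and -1.41, -1.43 and -1.435 without floor-water pituitary libraries 2, 3 and 4.

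Pituitary hormone genes stood higher in caged hypothalamus libraries. Pituitary tissue in the dissected hypothalamus is a candidate explanation: of 47 pituitary-restricted genes outside the lists, 87.2% had their highest hypothalamus level in caged library 4, which a change in the listed genes alone would not need. With the share of pituitary transcripts as a covariate the median of the hormone list was -0.123, but without caged library 4 (1.10) and without caged libraries 2 and 4 (1.22) it was still called. The 2 caged libraries then left have shares of 3.51% and 4.88%, above every floor-water library (0.511% to 1.56%), so this does not exclude pituitary tissue. An effect of housing or day length on these genes was not tested apart from it and stays open.

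Cilium and extracellular matrix genes stood higher in caged hypothalamus libraries. Pituitary tissue as the whole cause is argued against, since with its share as a covariate the medians were 1.45 and 0.57 and both calls held at the preset correlation. With an estimated correlation that fit called 0 lists. More ventricle wall or membrane in the caged dissections could raise both lists and cannot be told apart from housing: choroid plexus and astrocyte medians were 0.15 and 0.1, not past the threshold, but 0.44 and 0.22 and past it with the covariate. Housing and day length stay open, untested.

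Immediate early genes stood higher on average in caged pituitary libraries, though caged libraries 1 and 4 lay below floor-water libraries 1 and 2. Less brain tissue in the caged samples as the whole cause is argued against, since at the preset correlation the call held with the brain share as a covariate (median 0.83) and without the 3 libraries richest in brain transcripts, caged library 2 among them (0.39, down from 0.70). With an estimated correlation both fits called 0 lists. A single library carries much of the size: without caged library 2 the median was 0.28 (camera adjusted p = 9.4e-05). Housing, day length and handling before sampling stay open, untested; the last may act within minutes on these genes.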

How the results depend on the processing

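Fits with a tissue share as a covariate or without the libraries that stand apart were chosen after the data were seen. So were the newer quasi-likelihood fit, DESeq2 for the difference between tissues, and the genes named here outside the rule. The use of limma on FPKM with a pseudocount of 1 beside edgeR was added then as well. Counts of genes past an adjusted p of 0.05, 0 in edgeR for each comparison (1463, 670 and 1226 at an unadjusted p under 0.05), moved as follows, and the cause was not tested. The unadjusted counts moved by over 1.5 times in hypothalamus with the pituitary share as a covariate (965), in pituitary with all libraries in 1 fit (1329), for the difference in limma on FPKM (801) and, over fewer genes, with a filter of mean FPKM 2 (975, 432 and 689). In hypothalamus DESeq2 called 243, limma with quantile normalisation 1 (GPX3), all libraries in 1 fit 1 (CERKL) and the fit without both caged libraries that stand apart 6 (FOXN3, TMEM245, RLIM, MAP2K4, LOC101798753 and LOC113844800). Leaving out each library gave 0 to 1. In pituitary DESeq2 called 52, limma with array weights 2 (NFAT5, LOC110353286), all libraries in 1 fit 3 (CHRNA6, CTXND1, LOC110353286) and the newer quasi-likelihood 2 (LOC110353286, LOC113843336). Without each library in turn it was 0 to 2. For the difference between tissues DESeq2 called 142, array weights 11 and the title number as a random replicate block 1 (LOC110353286), and without each library in turn edgeR called 0 to 4.

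With an estimated correlation 0 lists were called in hypothalamus, 0 in pituitary and 0 for the difference between tissues, against 12, 15 and 17. The difference gave 2 with a filter of mean FPKM 2 and 1 without caged hypothalamus library 4, floor-water hypothalamus library 1 or floor-water pituitary library 4. Pituitary lists called ranged from 8 without floor-water library 2 to 19 without floor-water library 3. At an unadjusted p under 0.05, 69 genes overlapped between tissues in the same direction, against 0 at the adjusted threshold. The test direction reversed, with these medians, for reproductive axis (0.036, still above 0), pituitary hormone (-0.123) and neuron genes (0.073) in hypothalamus with the pituitary share as a covariate. In pituitary it reversed for cell cycle genes (-0.014) without the 3 libraries richest in brain transcripts, and for ribosomal proteins with array weights (-0.126) and without caged library 4 (-0.147; 0.14 without floor-water library 3). Medians of called lists also changed sign, with the call lost, for photoperiod (-0.031, the same covariate) and glucocorticoid genes (-0.015, without both caged libraries that stand apart) in hypothalamus. In pituitary this held for heat shock (-0.037) and oxidative phosphorylation genes (-0.026) with array weights and for neuropeptides without floor-water library 2 (0.068). The sterol median of the difference was -0.013 to -0.002 in limma with pseudocounts of 0.1, 0.5 and 1, with the random replicate block and without caged pituitary library 2, which alone lost the call. Among list results 2367 kept direction and side of the threshold, 121 came past it, 171 fell short of it and 6 reversed; among gene results 7317 kept theirs, 49 came past it and 0 reversed, where a reversal needs a value past the threshold, and 65 of 7366 gene values had the other sign.

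Between housings same-numbered libraries correlated at -0.02 to 0.088 in hypothalamus and -0.011 to 0.172 in pituitary (-0.013 to 0.155 and -0.105 to 0.23 over genes with a mean CPM of at least 1). In each tissue 3 of 8 libraries matched their own number best (3 and 2 over genes with a mean CPM of at least 1). This gives no clear sign of pairing by title number but does not exclude it, the pituitary libraries numbered 2 correlating at 0.172. Across tissues the range was 0.077 to 0.173, 6 of 8 pairs lay above 0.1, and 16 of 16 libraries matched their own number best (0.023 to 0.202, 5 of 8 and 13 of 16 over genes with a mean CPM of at least 1), a hint from the data that was not in the labels. The title number as a fixed replicate block called 0, 0 and 0 genes and 14, 15 and 19 lists. As a random block within housing in limma it called 1 gene and 15 lists for the difference between tissues. Depth (38853215 to 67175356 counts) limits low genes, and on simulated counts edgeR recovered 35% of genes changed 2-fold in hypothalamus, 21% in pituitary and 8% for the difference between tissues.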

Other observations

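The comparison with genes at least 10 times higher in the other tissue and the search for near-zero libraries were chosen after the results were seen, as were the splits that keep equal-numbered libraries together; the other splits were set before.

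Lists not called in the hypothalamus had these medians (camera adjusted p at the preset correlation in brackets): clock -0.15 (0.19), stress axis 0.03 (0.367), heat shock -0.11 (0.206), neuropeptides 0.10 (0.485), monoamine -0.08 (0.871), interferon 0.04 (0.522), inflammation 0.09 (0.0662), oxidative stress 0.04 (0.522), sterol 0.08 (0.432), feeding 0.04 (0.355), hypoxia -0.06 (0.355) and cell cycle 0.08 (0.355) genes. With single libraries left out some were called. Without caged library 2 these were the stress axis (-0.05, with the test upward), heat shock (-0.16), erythrocyte (-0.52) and lymphocyte (0.39) lists. Without floor-water library 1 they were the stress axis (0.08), neuropeptide (0.04) and microglia (0.24) lists. Inflammation genes were called without caged library 1 (0.22) or floor-water library 2 (0.07) or 3 (0.20). Oligodendrocyte markers were called without caged library 4 (-0.27) or floor-water library 2 (-0.26), astrocyte markers without caged library 4 (0.22), microglia markers without caged library 1 (0.21) and lymphocyte markers without floor-water library 4 (0.64). Cell type markers had medians of -0.28 for erythrocytes (0.3), -0.20 for oligodendrocytes (0.0662), 0.10 for astrocytes (0.308), 0.15 for choroid plexus (0.355), 0.16 for microglia (0.0889), 0.13 for endothelium (0.526), 0.41 for lymphocytes (0.08), -0.21 for skeletal muscle (0.355) and -0.04 for photoreceptors (0.594). In the clock list 17 of 19 genes lay below 0, and PER3, at 0.82, passed the threshold when adjusted over the list alone. So did 1 gene higher in the stress axis, oxidative stress, choroid plexus, microglia and endothelium lists each, and 1 lower oxidative stress gene.

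Lists not called in the pituitary were the clock -0.04 (0.0608), stress axis 0.01 (0.648), glucocorticoid response 0.01 (0.648), reproductive axis -0.08 (0.726), pituitary hormones 0.06 (0.165), photoperiod -0.07 (0.689), monoamine -0.19 (0.258), interferon -0.15 (0.648), inflammation -0.035 (0.455), oxidative stress -0.02 (0.648), hypoxia -0.05 (0.713) and ribosomal protein 0.02 (0.455) genes. Markers had medians of -0.47 for erythrocytes (0.132), -0.10 for neurons (0.689), -0.09 for endothelium (0.431), 0.015 for lymphocytes (0.163), -0.42 for photoreceptors (0.442) and -0.26 for folliculostellate cells (0.455). Without floor-water library 3 the clock (-0.12), monoamine (-0.24), ribosomal (0.14) and erythrocyte (-0.64) lists were called. Ribosomal genes were also called without caged library 2 (0.07), 3 (0.07) or 4 (-0.147). Called as well were erythrocyte (-0.62) and endothelial markers (-0.37) without floor-water library 4, and lymphocyte markers without caged library 2 (0.15) or 4 (0.24) or floor-water library 2 (0.22).

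Lists not called for the difference between tissues had median differences of 0.15 for clock (0.999), -0.54 for stress axis (0.0571), -0.52 for glucocorticoid response (0.052), -0.51 for monoamine (0.362), -0.58 for GABA and glutamate (0.0525), -0.17 for interferon (0.511), -0.25 for inflammation (0.47), -0.05 for oxidative stress (0.573), 0.04 for hypoxia (0.254) and 0.17 for cell cycle genes (0.254). Markers were at -0.315 for erythrocytes (0.616), 0.05 for neurons (0.0525), -0.28 for oligodendrocytes (0.0821), -0.26 for endothelium (0.0976), -0.36 for lymphocytes (0.579) and -0.65 for photoreceptors (0.0625). Leaving out single libraries brought some of these past the threshold. Stress axis genes were called without caged hypothalamus library 2 (-0.46), floor-water hypothalamus library 1 (-0.47), caged pituitary library 2 (-0.54), floor-water pituitary library 1 (-0.65) or 3 (-0.61). Glucocorticoid response genes were called without caged hypothalamus library 1 (-0.63) or 3 (-0.58), floor-water hypothalamus library 1 (-0.41) or 2 (-0.39), caged pituitary library 2 (-0.58) or 4 (-0.65), floor-water pituitary library 3 (-0.33) or 4 (-0.52). GABA and glutamate genes were called without caged hypothalamus library 4 (-0.58), floor-water hypothalamus library 1 (-0.585), caged pituitary library 2 (-0.94), floor-water pituitary library 1 (-0.74) or 3 (-0.74). Neuron genes were called without caged hypothalamus library 1 (0.11) or 2 (0.11), floor-water hypothalamus library 4 (0.08), caged pituitary library 1 (0.16) or 3 (0.08) or 4 (0.17), floor-water pituitary library 2 (0.24) or 4 (0.23). Oligodendrocyte genes were called without caged hypothalamus library 3 (-0.32), floor-water hypothalamus library 4 (-0.45), caged pituitary library 2 (-1.72), floor-water pituitary library 1 (-0.59) or 3 (-0.41). Endothelial genes were called without caged hypothalamus library 3 (-0.26), floor-water hypothalamus library 4 (-0.35), caged pituitary library 4 (-0.48), floor-water pituitary library 4 (-0.37). Photoreceptor genes were called without caged hypothalamus library 3 (-0.84) or 4 (-0.44), caged pituitary library 4 (-0.56), floor-water pituitary library 3 (-0.74). The monoamine list was called without floor-water hypothalamus library 4 (-0.63), and the cell cycle list without caged pituitary library 4 (0.29) or floor-water pituitary library 3 (0.31).

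Of the genes the authors' deposited table marks as higher in caged hypothalamus, 439 were tested here and 183 (41.7%) had a mean in pituitary of at least 10 CPM and at least 10 times their median over hypothalamus libraries. This held for 260 of 15736 tested genes (1.7%, Fisher's exact p = 2.44e-237, genes not being independent). Among all 445 genes so marked in the authors' deposited table, the highest caged library was library 4 for 229 and libraries 1 to 3 for 36, 90 and 90. Of the genes the authors' deposited table marks as lower in caged pituitary, 249 were tested here and 33 (13.3%) were at least 10 times higher in hypothalamus by the same measure, against 447 of 15582 (2.9%, Fisher's exact p = 1.99e-13).

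Other splits of the libraries into groups of the same size were tested. In hypothalamus the 1463 genes at an unadjusted p under 0.05 exceeded every other split (highest 1370). That is 1 of 35 splits, the smallest share this test can give. It is unadjusted over the several counts judged, so it alone does not exclude chance. With the pituitary share as a covariate the count was 965, a fit not run on the other splits. Chance is not excluded for the 12 lists (7 of 35, highest other 16). In pituitary chance cannot be excluded for the 670 genes (14 of 35; highest other 1630) or the 15 lists (2 of 35; highest other 18). For the difference between tissues, 3 of 100 drawn splits called as many as the 17 lists (other splits called 18 and 19). This share is small but unadjusted over the counts judged. Chance cannot be excluded for the 1226 genes (24 of 100, highest other 2317). The list counts hold at the preset correlation only: with an estimated one the real grouping called 0 lists and the other splits up to 7. These splits drew each tissue independently. With equal-numbered libraries of a housing kept together, the 17 lists stood 1 list above the highest of the other splits (16). That is again 1 of 35, the smallest share possible, by a narrow margin and at the preset correlation only. With an estimated one the real grouping called 0 lists and other splits up to 7, so chance is not excluded there. Nor can it be excluded for the 1226 genes (7 of 35, highest other 1614). Every split reaches a count of 0, so the 0 genes called in edgeR (35 of 35 in each tissue, 100 of 100 and 35 of 35 for the difference) decide nothing on chance. The highest of the other splits were 3, 2, 89 and 38, and DESeq2 was not run on the splits. Splits calling 89 or 38 genes point to a structure of the samples. The split calling 89 set the 4 pituitary libraries with brain shares of 0.29% to 0.615% apart from those with 1.03% to 6.14%; whether this made its calls was not tested.

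Single libraries at least 8-fold below a median of 20 CPM or more occurred for 47 of 7197 genes in hypothalamus, most (16) in caged library 4, and for 50 of 7031 in pituitary, most (18) in caged library 4.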
